A study of Mus musculus with 6 samples.

How the data were processed

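Gene expression was measured by RNA sequencing in 6 libraries labelled as primary cardiac fibroblasts of C57BL/6J mice. The series compares untreated control mice with mice given carbon tetrachloride (CCl4), a solvent whose liver metabolism produces free radicals and whose repeated dosing scars the liver, with 3 mice and 3 libraries in each of the 2 groups. Dose, duration and route of CCl4, the sex of the mice, and the method of fibroblast isolation are not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was captured on oligo(dT) beads, the second strand was marked with uracil and degraded so that libraries keep strand, and the libraries were read from both ends. Oligo(dT) capture favours polyadenylated transcripts, so histone mRNAs and other transcripts without a tail are under-represented.

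The deposited table holds FPKM values (fragments per kilobase of gene model, scaled to the mapped fragments of the library), which the authors made with StringTie 2.1.6 on the mouse build GRCm38, per the submitters' processing notes. The aligner, the annotation release, any filter and the strand setting of the quantification are not given in the sources used here. The table has 32479 rows with 32415 distinct symbols and 1 column per library, at 2 decimals, and no columns of other samples. The FPKM sums differed between libraries, from 519609 to 602763, so the values had not been rescaled to a common sum. A fixed budget of fragments means that a few very abundant transcripts lower the FPKM of the others, and about 50% of each sum came from the 37 rows of the mitochondrial genome, which is why other scalings were tried.

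Fragment counts were not used here. For 3561 single-exon genes of 300 to 1200 bp, low values above 0 were multiplied by gene length, which left 751 to 958 values per library. The most frequent product within a preset range was taken as 1 fragment. That gave a rough estimate of 39200000 to 42000000 fragments in the control libraries and 30800000 to 38500000 in the CCl4 libraries. Only 29.2% to 37.2% of the low values lay within 10% of a whole number of fragments, where 20% of evenly spread values would. Setting 1 fragment at the most frequent product raises that share by itself. No count test was therefore run, and depth is known only as this estimate. At such a depth 1 FPKM over 1 kb of transcript corresponds to 30.8 to 42.0 fragments.

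Values were transformed to log2(FPKM + 1), and rows with a mean FPKM of at least 1 over the 6 libraries were kept, which left 10995 rows. Fold changes are on this log2(FPKM + 1) scale and understate the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all rows tested. A gene was called at an adjusted p under 0.05 with no fold threshold. Gene values are given as mean FPKM ± SD over 3 libraries, and log2 fold changes as CCl4 minus control with their standard error (SE).

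Before the data were examined, 38 gene lists were fixed, 25 for pathways, 12 for cell types that a heart preparation can hold and 1 for mitochondrially encoded transcripts. The 32 lists with at least 5 tested members were compared with the other genes by camera in limma with a preset inter-gene correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation. The fry test in limma, which asks whether the members of a list move on balance in 1 direction, was run as an alternative. For each list the number of called members is given over all genes tested, and the number adjusted over the list alone.

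Genes were named by a rule fixed at the same time. It took the 15 largest rises and 15 largest falls among called genes whose groups did not overlap, leaving out predicted genes and pseudogenes. It also took up to 4 members of each list with the smallest p, further called members, the most abundant markers of each cell type, and 18 genes named whatever their result. Some of the genes taken by these rules are not reported here. Apln, Bmp10, Sln, Myl7, Myl4 and Nppa were singled out after their values were seen. Single measures per library were compared by two-sided exact permutation tests, which with 3 against 3 libraries cannot give a p below 0.1.

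Symbols were matched to GENCODE M21, the GRCm38 annotation used here for positions. Of all rows, 96.82% matched, 167 tested rows did not, and 60 symbols stood on more than 1 row. Rows carry symbols without gene identifiers, so a position given for a symbol is that of its GENCODE gene and not of a model recorded in the table.

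Alternatives comprised pseudocounts of 0.1 and 0.01, no filter or a mean FPKM of at least 5, rescaling to a common sum per library (TPM), trimmed mean of M-values (TMM), quantile and median-ratio scaling, limma without trend, with robust variances or with library weights, the replicate number as a block, and leaving out each library in turn. A rescaling without mitochondrial rows and 7 nuclear pseudogenes that copy them was added after the data were seen. The procedure was tested on simulated data for this comparison with 200 of 10995 genes changed in each of 5 runs. It recovered 54.9% of changes of 0.5 on the log2 scale, 91.6% of changes of 1 and 98.2% of changes of 2, and 4.99% of calls were false. The simulated errors were independent between genes, and far fewer genes were changed than were called in the data. These rates therefore need not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and the size of 1 fragment was estimated with scipy 1.17.1.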

Results

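The data comprised 6 RNA sequencing libraries from hearts of C57BL/6J mice, 3 from control mice and 3 from mice given CCl4 to model liver cirrhosis, each labelled as isolated cardiac fibroblasts. The series was designed to ask how cirrhosis acts on the heart, through its fibroblasts, the cells that make and remodel the collagen matrix between muscle cells. Each library came from its own mouse, as far as the design text states it. An estimated 30800000 to 42000000 fragments stood behind each library. Between 21054 and 22395 rows per library had an FPKM above 0, and 10737 to 11220 had at least 1.

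Transcripts of heart muscle cells and of mitochondria made up much of every library. The 37 rows of the mitochondrial genome, 13 of them protein-coding, took 49.96% ± 1.17 of the FPKM sum in control libraries and 52.7% ± 0.595 in CCl4 libraries (SD, n = 3 each; two-sided exact permutation test, p = 0.1, the smallest this design allows). Another 7 rows are nuclear pseudogenes on chromosome 1 that share 97.2% to 100% of their 31-base words with mitochondrial transcripts. With them the share was 67.3% ± 1.80 and 71.7% ± 0.304 (SD, n = 3 each; exact permutation p = 0.1). Of the sum left without these 44 rows, the 32 genes of the cardiomyocyte list took 13.8% ± 0.291 and 16.8% ± 0.744 (SD, n = 3 each; exact permutation p = 0.1). The 21 genes of the fibroblast list took 0.408% ± 0.103 and 0.468% ± 0.00731 (SD, n = 3 each; exact permutation p = 0.4). Mb, the muscle oxygen carrier myoglobin, averaged 4073 FPKM, and Pln, the phospholamban that restrains the calcium pump of heart muscle, 1781 FPKM, against 10.6 FPKM for Col1a1, 3.78 FPKM for Pdgfra and 2.60 FPKM for Tcf21, markers of cardiac fibroblasts. Among tested genes outside these 44 rows Col1a1 stood at the 76.5th percentile and Tcf21 at the 31.4th, while Gsn and Dcn, also fibroblast markers, stood at the 99.6th and 97.6th. Such a share is a sum, so single abundant genes weigh heavily in it. Of the cardiomyocyte list Actc1 rose from 1735 ± 477 to 5840 ± 261 FPKM, while Myh7 fell from 955 ± 574 to 71.2 ± 9.84 FPKM. The median FPKM over the cardiomyocyte list went the other way from its share. It was 542.5 ± 52.9 in control and 496.6 ± 25.8 in CCl4 libraries (SD, n = 3 each, exact permutation p = 0.3). That median was 87.8 ± 14.1 times that over the fibroblast list in control and 36.1 ± 2.88 times in CCl4 libraries (SD, n = 3 each, exact permutation p = 0.1). A family of 10 such library measures was tested, and with this smallest p none can pass 0.05 before or after adjustment.

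**Figure D1:**
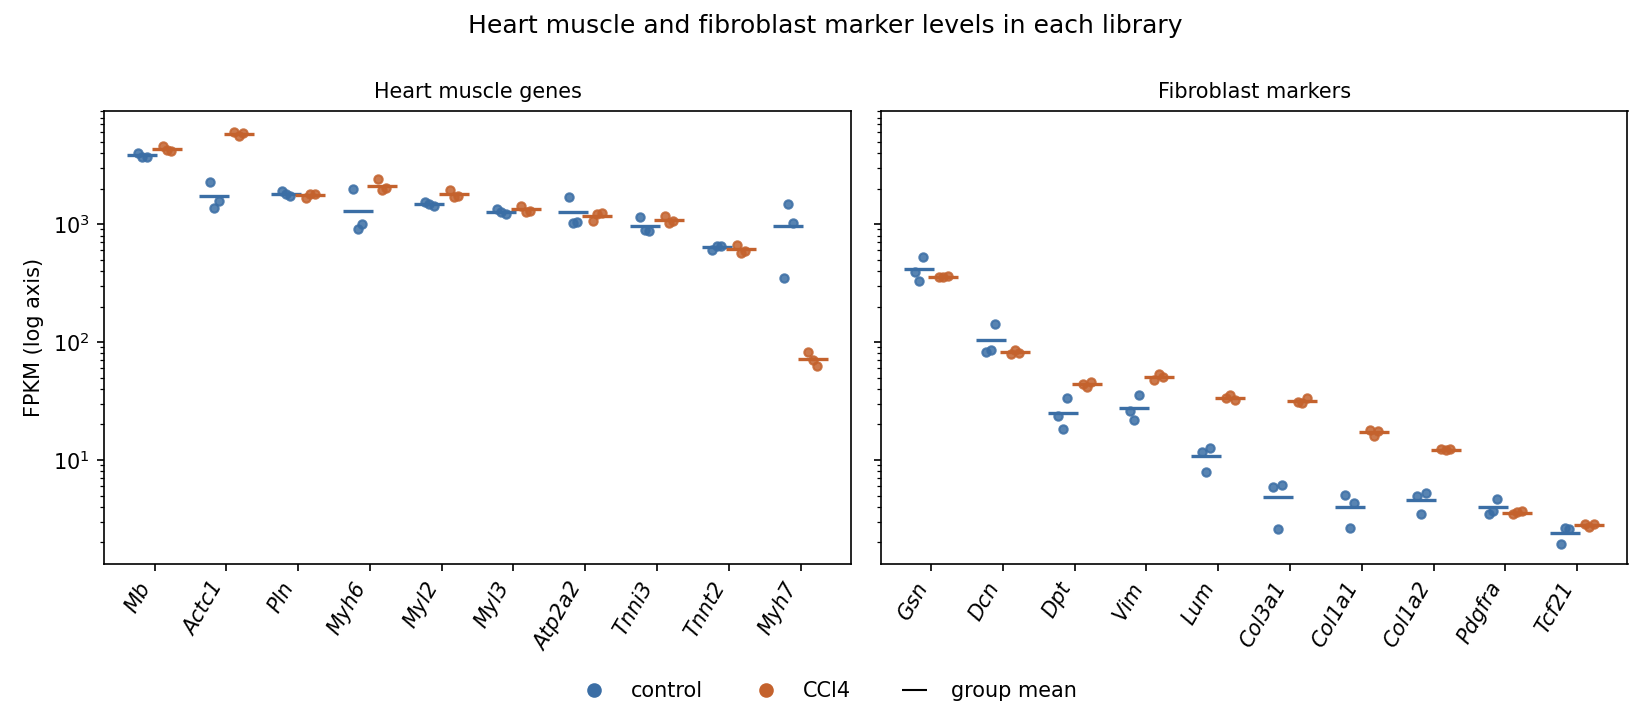
FPKM on a log axis of 10 heart muscle genes (left) and 10 fibroblast markers (right) in each of the 6 libraries, with points for single libraries and bars for group means (blue, control; orange, CCl4; n = 3 each). Tnnt2, the lowest heart muscle gene shown apart from Myh7, averaged 635 FPKM in control and 610.6 in CCl4 libraries, while Col1a1 averaged 4.02 and 17.2 FPKM.

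The comparison of CCl4 with control asks which genes of the heart preparation differ in mice given CCl4 to model liver cirrhosis. Liver scarring itself was not measured in these data. In CCl4 libraries collagen genes were higher, led by Col3a1, which rose from 4.88 ± 1.97 to 31.6 ± 1.47 FPKM (SD, n = 3 each), and Col1a1, which rose from 4.02 ± 1.24 to 17.2 ± 1.11 FPKM. Genes of fatty acid use fell, led by Pdk4, the kinase that turns off pyruvate oxidation during fasting, from 374.9 ± 82.7 to 19.8 ± 2.48 FPKM. Immediate early genes, which switch on within minutes of a stimulus, fell in 25 of the 27 tested, with Nr4a1 at 54.9 ± 24.8 and 2.36 ± 0.998 FPKM. Of single genes of the sarcomere, the contractile unit of muscle, the slow myosin Myh7 fell from 955 ± 574 to 71.2 ± 9.84 FPKM and the cardiac actin Actc1 rose from 1735 ± 477 to 5840 ± 261 FPKM. Of ribosomal protein genes 48 of 69 were lower. Of endoplasmic reticulum stress genes it was 22 of 32. Of the fixed lists that hold these genes, only that of fatty acid genes was called by camera with an estimated correlation.

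In all, 3501 of 10995 tested rows (31.8%) passed an adjusted p of 0.05 in limma, 1060 higher and 2441 lower in CCl4. Without adjustment, 4894 rows lay under 0.05. The groups did not overlap for 3479 of the called rows and for 48.7% of all tested rows, where chance gives 10%. The first principal component held 66.2% of the variance and placed control libraries between -23.6 and -17.4 and CCl4 libraries between 18.3 and 22.4. Correlations of log2 values across genes, which are not independent replicates, were 0.983 to 0.991 within groups and 0.954 to 0.968 between them. The balance of directions depended on scaling. The higher share of calls was 30.3% for FPKM as deposited, 12.8% after rescaling to TPM (617 higher, 4221 lower), 51.4% with TMM (1700 and 1605), 51.2% with quantile (1722 and 1641) and 52.1% with median-ratio scaling (1713 and 1574). With the mitochondrial rows and the 7 pseudogene rows removed it was 40.9% (1322 and 1914). The median log2 fold change over tested genes was -0.09 as deposited, -0.23 as TPM and -0.00477 with TMM, and changes of whole groups are to be read relative to that shift. As TPM 27 of the 32 lists had more lower members and 20 had fewer higher members. With TMM 19 had more higher and 17 fewer lower members, and the sign of the median turned in 5 lists as TPM and in 7 with TMM. Of the 32 lists tested with camera, 10 were higher and 7 lower, and only the fatty acid list kept an adjusted p under 0.05 with an estimated correlation.

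**Figure D2:**
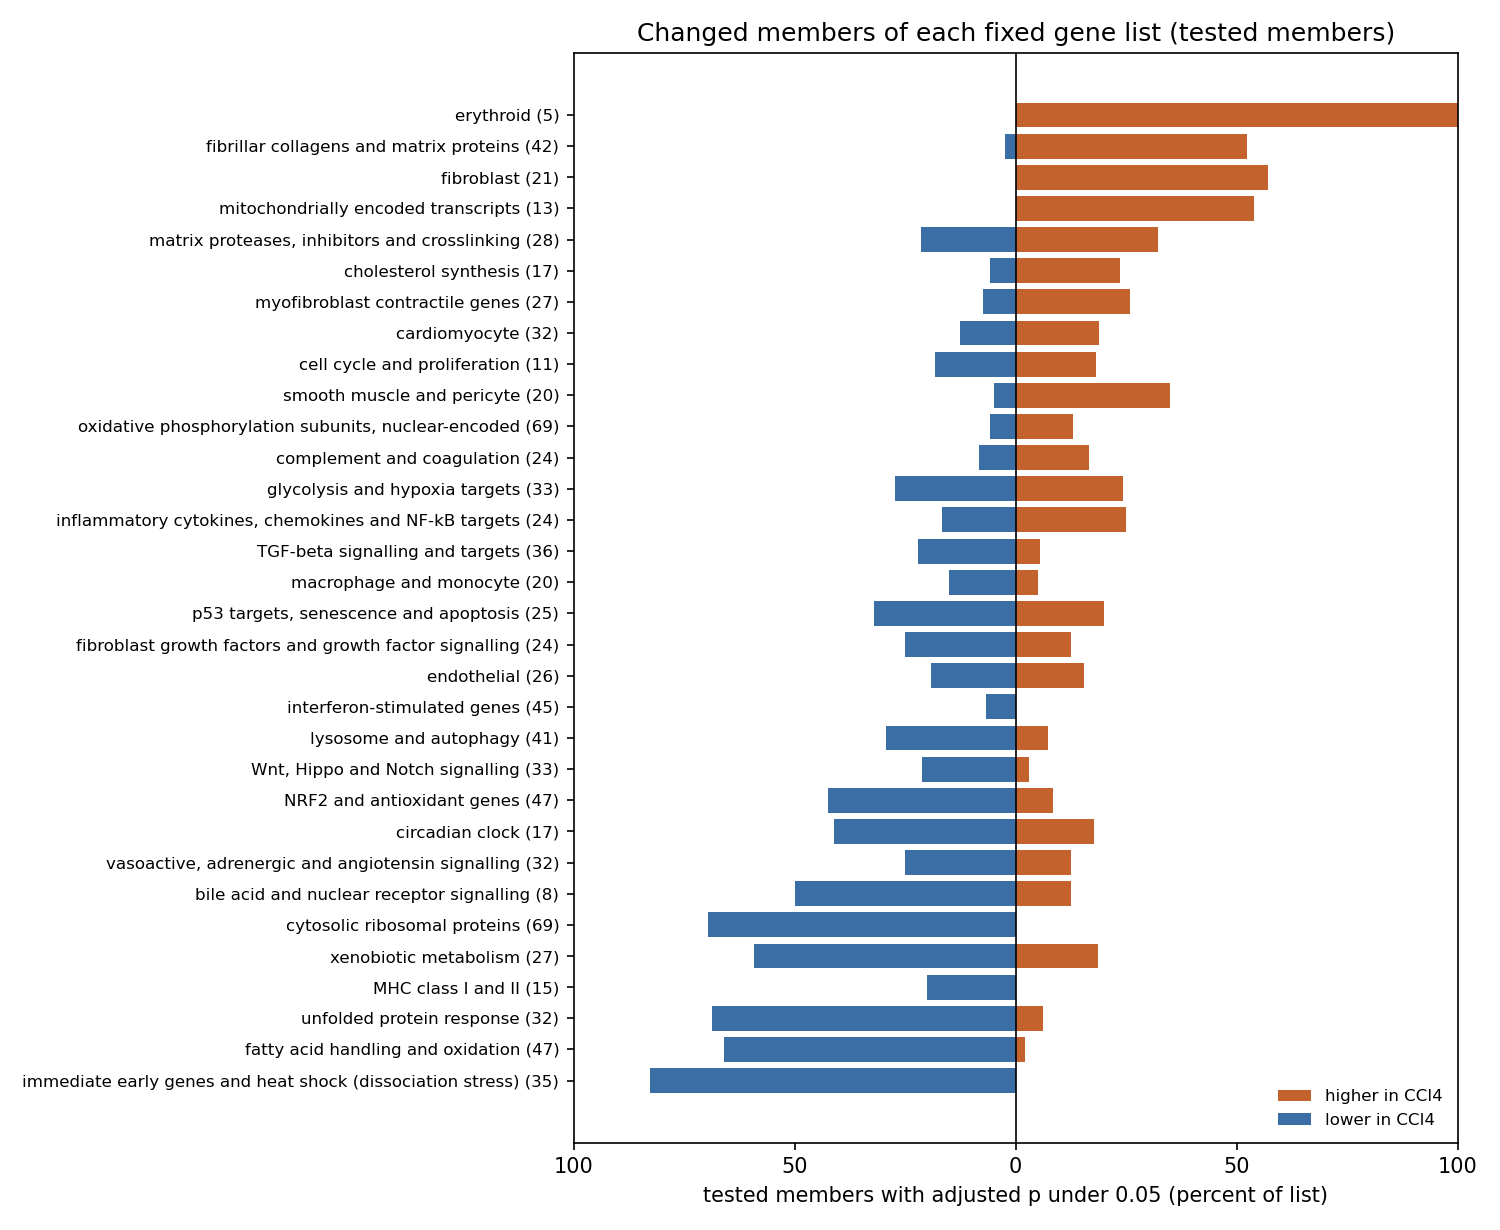
Share of the tested members of each fixed gene list (number tested in brackets) with an adjusted p under 0.05, higher in CCl4 to the right and lower to the left, in percent of the list, ordered by median log2 fold change. Of the collagen and fibroblast lists 22 of 42 and 12 of 21 members were higher, and of the fatty acid and the immediate early and heat-shock lists 31 of 47 and 29 of 35 were lower.

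Matrix genes rose in CCl4. Of 42 tested collagen and matrix genes, 22 rose and 1 fell (26 and 2 adjusted over the list alone), with a median log2 fold change of 0.53 (camera adjusted p = 8.29e-12; adjusted p = 0.584 with an estimated correlation). Fry did not call this list (fry adjusted p = 0.067). Col3a1, on chromosome 1 at 45311538 to 45349706 in GRCm38, had a log2 fold change of 2.54 ± 0.23 (SE; adjusted p = 0.000326). Col1a1, on chromosome 11 at 94936224 to 94953042, had 1.88 ± 0.17 (adjusted p = 0.000312), and its partner chain Col1a2 rose by 1.27 ± 0.12 (adjusted p = 0.000397). Col15a1, a collagen beside basement membranes, and the collagen VI chains Col6a2 and Col6a3 rose by 2.07, 1.39 and 1.40. Sparc, a collagen-binding protein, rose from 36.3 ± 7.64 to 75.8 ± 2.75 FPKM. The fibronectin gene Fn1 was at 3.45 ± 1.02 and 4.94 ± 0.56 FPKM and did not pass (adjusted p = 0.0726), but passed with TMM (adjusted p = 0.0347), quantile (0.0349) and median-ratio scaling (0.0329), with library weights (0.0313) and without control replicate 3 (0.0247).

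Among 28 matrix proteases, inhibitors and crosslinking genes, 9 rose and 6 fell (9 and 6 adjusted over the list alone; median 0.23, camera adjusted p = 0.00446; adjusted p = 0.653 with an estimated correlation). Pcolce, which aids removal of the procollagen tail, rose by 1.27 ± 0.15 (SE), and Serpinh1, the collagen chaperone, by 0.83 ± 0.11. The protease Adamts1 fell by 1.38 ± 0.18 and the protease inhibitor Timp3 by 0.86 ± 0.14. The inhibitor Timp1 was at 1.65 ± 0.693 and 2.57 ± 0.925 FPKM (adjusted p = 0.177). The gelatinase Mmp2 was at 14.5 ± 4.8 and 22.2 ± 0.679 FPKM (log2 fold change 0.63, adjusted p = 0.038), a call lost when any library but control replicate 3 was left out (0.42 to 0.65, adjusted p 0.076 to 0.0965), as TPM (adjusted p = 0.0686), with no filter (0.124) and with robust variances (0.0528). Without CCl4 replicate 2 the number of higher members was 5, as it was with TPM, and the list's call was lost among genes with a mean FPKM of at least 5 (adjusted p = 0.141).

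Of 21 fibroblast markers, 12 rose and none of the rest fell (13 adjusted over the list alone; median 0.41, camera adjusted p = 1.15e-07; adjusted p = 0.584 with an estimated correlation). Collagens were 3 of these 12. The list was not called by fry (fry adjusted p = 0.0627). Lum, a collagen-binding proteoglycan, rose from 10.7 ± 2.42 to 33.8 ± 1.89 FPKM, Vim from 27.8 ± 6.96 to 50.6 ± 2.63 FPKM, and Cd34, also made by endothelial cells, from 9.09 ± 2.27 to 18.8 ± 1.53 FPKM. The most abundant markers Gsn and Dcn were at 413.9 ± 99.4 and 103 ± 33.4 FPKM in control and 358 ± 3.38 and 81.7 ± 3.67 FPKM in CCl4 libraries (adjusted p = 0.391 and 0.274). The receptor Pdgfra and the transcription factor Tcf21, markers of resident fibroblasts, had log2 fold changes of -0.11 ± 0.10 and 0.17 ± 0.10 (adjusted p = 0.428 and 0.212). Without control replicate 3, the median of the list was 0.72.

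Contractile genes of myofibroblasts, the activated state of fibroblasts, rose in 7 of 27 members and fell in 2 (7 and 2 adjusted over the list alone; median 0.13, camera adjusted p = 0.00653; adjusted p = 0.668 with an estimated correlation). The fixed lists of myofibroblast genes and of smooth muscle and pericyte genes share Acta2, Tagln, Cnn1, Mylk, Actg2, Lmod1 and Des. Their results are therefore not independent. Acta2, the smooth muscle actin of myofibroblasts and vessel walls, rose from 21.8 ± 2.37 to 46.6 ± 7.97 FPKM (adjusted p = 0.0013), and the tropomyosin Tpm4 from 12.8 ± 0.836 to 23.5 ± 1.43 FPKM. The 2 falls were Des, an intermediate filament of muscle, from 516 ± 47.0 to 301 ± 5.75 FPKM, and the integrin Itgb5, from 46.7 ± 5.06 to 25.2 ± 2.14 FPKM. Tagln was at 9.36 ± 0.904 and 13.2 ± 6.14 FPKM (log2 fold change 0.34, adjusted p = 0.428), and at 0.76 (adjusted p = 0.00714) without CCl4 replicate 1. Postn, a matrix protein of activated fibroblasts, was at 4.17 ± 3.79 and 11.4 ± 1.04 FPKM (1.51, adjusted p = 0.0279), a call lost when any library but control replicate 3 was left out (1.07 to 1.58, adjusted p 0.0604 to 0.0854), with no filter (0.109) and with robust variances (0.102). The list's median was 0.21 without CCl4 replicate 1 and 0.01 as TPM (0.00924), the number of higher members was 4 without CCl4 replicate 2 or without CCl4 replicate 3, and the call was lost among genes with a mean FPKM of at least 5 (adjusted p = 0.0654).

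TGF-beta genes did not move as a group. Of 36 members 2 rose and 8 fell (2 and 8 adjusted over the list alone; median -0.01, camera adjusted p = 0.536, with a test direction opposite to the median). Ccn2, a target of TGF-beta and of mechanical strain, fell from 86.4 ± 20.5 to 14.1 ± 2.55 FPKM, and Ccn1 fell by 0.73 ± 0.15 (SE). Fstl1, a secreted follistatin-like protein, rose by 0.92 ± 0.20. Tgfb1 itself was at 2.68 ± 0.501 and 3.29 ± 0.0808 FPKM (adjusted p = 0.129; 0.0388 without control replicate 3). Without control replicate 3, 9 members of the list were higher and 7 lower, and without CCl4 replicate 2 or CCl4 replicate 3 it was 5 that were lower. With TMM 6 were higher and 6 lower. In the list of Wnt, Hippo and Notch genes, 1 of 33 rose and 7 fell (1 and 6 adjusted over the list alone; median -0.15, camera adjusted p = 0.541), among them Amotl2, a target of the Hippo effector YAP, which fell by 1.07 ± 0.11. Without control replicate 2 that list had 0 higher and 4 lower members, and without control replicate 3 it had 8 and 6. As TPM 13 were lower.

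**Figure D3:**
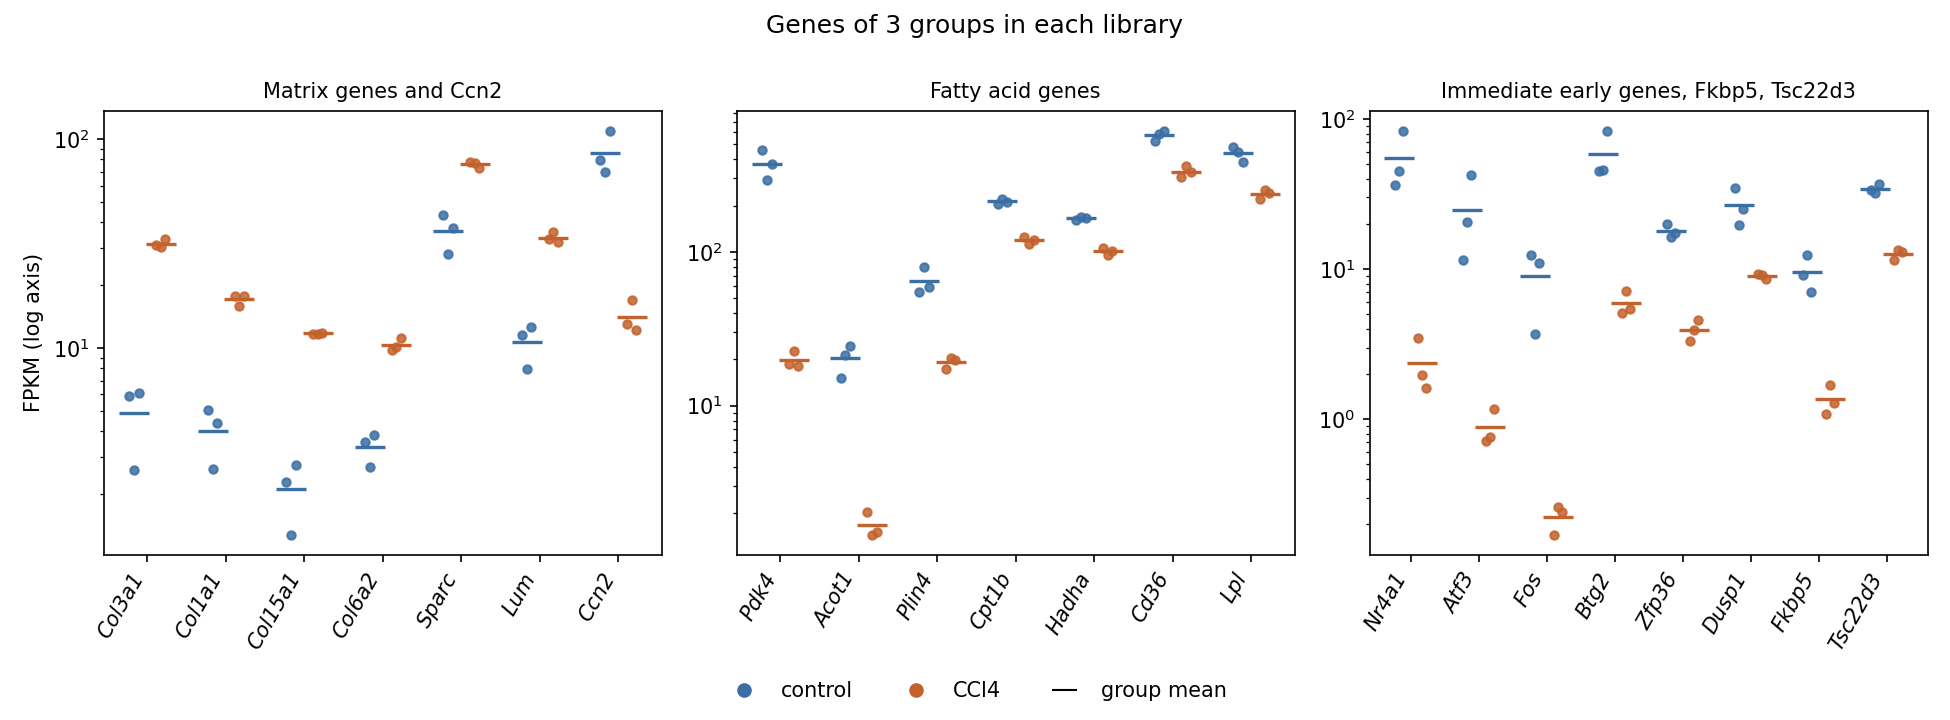
FPKM on a log axis of 6 matrix genes and the TGF-beta target Ccn2 (left), 7 fatty acid genes (middle) and 8 immediate early and glucocorticoid-responsive genes (right) in each of the 6 libraries, with points for single libraries and bars for group means (blue, control; orange, CCl4; n = 3 each). The points of the groups do not overlap for any gene shown, with the 6 matrix genes at left higher in CCl4 and the other genes lower.

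Fatty acid genes fell in 31 of 47 members and rose in 1 (34 and 1 adjusted over the list alone; median -0.52, camera adjusted p = 1.8e-09; adjusted p = 0.0498 with an estimated correlation). Pdk4, on chromosome 6 at 5483351 to 5496309, fell by 4.16 ± 0.16 (SE; adjusted p = 1.72e-05). The acyl-CoA thioesterase Acot1, whose sequence is close to that of Acot2, fell from 20.4 ± 4.82 to 1.67 ± 0.317 FPKM. The triglyceride lipase Pnpla2 fell from 200.4 ± 14.3 to 73.2 ± 3.53 FPKM and the lipid droplet protein Plin4 by 1.68 ± 0.14. The oxidation enzymes Cpt1b and Hadha fell by 0.84 ± 0.08 and 0.71 ± 0.08, and the uptake genes Cd36 and Lpl by 0.78 and 0.87. Most of these genes are abundant in heart muscle, whose markers changed in both directions.

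Glycolysis and hypoxia genes were split, with 8 of 33 higher and 9 lower (10 and 11 adjusted over the list alone; median -0.01, camera adjusted p = 0.346). The stress-induced Ddit4, an inhibitor of mTOR signalling, fell from 34.9 ± 3.60 to 6.45 ± 1.28 FPKM, and Bnip3, a mitophagy receptor, from 168 ± 42.1 to 43.0 ± 2.57 FPKM. The glycolytic enzymes Pkm and Hk2 rose by 0.64 ± 0.11 and 0.53 ± 0.12 (SE). Without control replicate 2 or CCl4 replicate 3 the list had 5 lower members. It had 5 higher and 13 lower as TPM, and 11 and 5 with TMM or median-ratio scaling. Among nuclear-encoded oxidative phosphorylation subunits 9 of 69 rose and 4 fell (6 and 4 adjusted over the list alone; median 0.05, camera adjusted p = 0.00446; adjusted p = 0.856 with an estimated correlation). As TPM the median was -0.10 and the call was lost (adjusted p = 0.0664), with 2 higher and 14 lower. The call was also lost without control replicate 3 (median 0.00198, adjusted p = 0.0717) and without CCl4 replicate 1 (0.000809, adjusted p = 0.218). With TMM 15 were higher and 0 lower, and with quantile scaling 23 and 3. Higher members numbered 20 without control replicate 1, 3 without control replicate 2, control replicate 3 or CCl4 replicate 1, 5 without CCl4 replicate 2 and 2 without CCl4 replicate 3. The 13 mitochondrially encoded genes had 7 higher members and 0 lower (9 adjusted over the list alone; median 0.30, camera adjusted p = 5.37e-05; adjusted p = 0.584 with an estimated correlation), with mt-Atp6 at 0.42 ± 0.09 and mt-Nd2 at 0.50 ± 0.11. Without control replicate 2, 4 were higher. As TPM 4 were higher, with a median of 0.14, and with no filter none was called. With quantile scaling, which fixes the top ranks, the median was 0 with 1 higher and 3 lower. In cholesterol synthesis 4 of 17 genes rose and 1 fell (3 and 1 adjusted over the list alone; median 0.14, camera adjusted p = 0.00743; adjusted p = 0.61 with an estimated correlation), led by the mevalonate enzyme Pmvk, from 2.44 ± 0.32 to 13.4 ± 1.18 FPKM, while the squalene synthase Fdft1 fell by 0.45 ± 0.10. The median was 0.05 without control replicate 2 and 0.02 as TPM.

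Antioxidant and detoxification genes were lower. Of 47 NRF2 and antioxidant genes 20 fell and 4 rose (22 and 4 adjusted over the list alone; median -0.21, camera adjusted p = 0.0308; adjusted p = 0.506 with an estimated correlation). The peroxide-degrading catalase Cat fell from 122 ± 11.2 to 61.8 ± 2.94 FPKM, the metallothioneins Mt1 and Mt2, also induced by glucocorticoids, by 1.46 ± 0.14 and 1.74 ± 0.17 (SE), and the superoxide dismutase Sod1 by 0.78 ± 0.08. The call was lost without CCl4 replicate 2 (adjusted p = 0.0581), with quantile scaling (0.0826) and at a mean FPKM of at least 5 (0.105). The list had 2 higher members without control replicate 2, control replicate 3 or CCl4 replicate 3 and with no filter, and 2 higher and 27 lower as TPM. Its median was -0.37 as TPM, -0.11 with TMM and -0.09 with quantile scaling. Of 27 xenobiotic genes 16 fell and 5 rose (17 and 5 adjusted over the list alone; median -0.37, camera adjusted p = 0.0392; adjusted p = 0.653 with an estimated correlation), with the sulfotransferase Sult1a1 falling from 37.8 ± 2.50 to 14.5 ± 1.85 FPKM and the flavin monooxygenase Fmo2 by 1.44 ± 0.18. That call was lost without control replicate 2 (adjusted p = 0.071), CCl4 replicate 2 (0.0505) or CCl4 replicate 3 (0.0694, with 10 lower) and as TPM (0.107).

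Immediate early and heat-shock genes, a set that also responds to tissue dissociation, fell in 29 of 35 members and rose in 0 (30 and 0 adjusted over the list alone; median -1.03, camera adjusted p = 7.03e-10; adjusted p = 0.584 with an estimated correlation). Nr4a1, on chromosome 15 at 101254269 to 101274795, fell by 4.01 ± 0.30 (SE; adjusted p = 0.00015). Atf3 fell from 24.9 ± 16.0 to 0.883 ± 0.249 FPKM, Fos from 9.02 ± 4.67 to 0.223 ± 0.0473 FPKM, and the antiproliferative gene Btg2 from 58.1 ± 21.5 to 5.90 ± 1.09 FPKM. Zfp36, which destabilises cytokine mRNAs, and the phosphatase Dusp1 fell by 1.95 ± 0.12 and 1.43 ± 0.17. Of 32 genes of the unfolded protein response 22 fell and 2 rose (23 and 2 adjusted over the list alone; median -0.44, camera adjusted p = 8.29e-05; adjusted p = 0.506 with an estimated correlation), including the chaperone Hsp90b1, by 0.83 ± 0.11, the lectin chaperone Canx, by 0.71 ± 0.09, and the phosphatase subunit Ppp1r15a, by 1.39 ± 0.15. Cytosolic ribosomal protein genes fell in 48 of 69 members and rose in 0 (57 and 0 adjusted over the list alone; median -0.35, camera adjusted p = 1.23e-09; adjusted p = 0.653 with an estimated correlation), with Rps9 falling from 94.0 ± 2.74 to 62.6 ± 2.71 FPKM. The lower members numbered 17 with TMM or median-ratio scaling, 23 with quantile scaling, 31 without control replicate 2, 27 without CCl4 replicate 2 and 25 without CCl4 replicate 3.

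Of 25 p53, senescence and apoptosis genes 8 fell and 5 rose (8 and 5 adjusted over the list alone; median -0.06, camera adjusted p = 0.81; fry adjusted p = 0.0174). The cell cycle inhibitor Cdkn1a fell from 12.8 ± 2.45 to 3.36 ± 0.497 FPKM, and the apoptosis genes Fas and Bcl2l1 by 1.15 ± 0.11 and 1.80 ± 0.17 (SE). Of 65 cell cycle genes only 11 were expressed enough to test, with 2 higher and 2 lower (2 and 2 adjusted over the list alone; median 0.08, camera adjusted p = 0.193). The cyclin Ccnd1 rose from 4.93 ± 0.481 to 13 ± 0.416 FPKM and the centromeric histone Cenpa by 1.06 ± 0.09. With no filter on low values this list passed (adjusted p = 6.06e-09), with 5 higher and 1 lower. Without control replicate 2 (median -0.01) or CCl4 replicate 3 it had 0 lower members, and without any other single library 1. Clock genes were lower in 7 of 17 and higher in 3 (9 and 4 adjusted over the list alone; median -0.23, camera adjusted p = 0.564). The period gene Per1, also induced by glucocorticoids, fell from 20.3 ± 2.87 to 6.08 ± 0.671 FPKM, whereas Dbp, a transcription factor driven by the clock, rose from 21.7 ± 5.60 to 48.8 ± 0.828 FPKM. Of 41 lysosome and autophagy genes 12 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.13, camera adjusted p = 0.417; fry adjusted p = 0.0213), with the cathepsin Ctsl falling by 0.96 ± 0.08. That list had 1 higher member without control replicate 2 or CCl4 replicate 3, 1 higher and 19 lower as TPM, and 6 and 10 with TMM. Its median was -0.06 without control replicate 1, -0.28 as TPM and -0.03 with TMM.

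Of the immune lists only that of MHC genes was called. Of 24 cytokine, chemokine and NF-kB genes 6 rose and 4 fell (6 and 4 adjusted over the list alone; median -0.01, camera adjusted p = 0.193, with a test direction opposite to the median; adjusted p = 0.0451 without control replicate 3). The chemokines Cxcl14, Cxcl12 and Ccl11, made by fibroblasts among other cells, rose by 1.39 ± 0.18, 0.88 ± 0.12 and 0.82 ± 0.11 (SE), and Nfkbia, the inhibitor that NF-kB itself induces, fell from 23.2 ± 1.44 to 10.2 ± 0.397 FPKM. The list had 4 higher members without control replicate 2 or any single CCl4 library. Il6 lay between 0 and 0.02 FPKM and Ccl2 between 0.27 and 1.82 FPKM in single libraries, below the filter. Of 45 interferon-stimulated genes 0 rose and 3 fell (0 and 2 adjusted over the list alone; median -0.09, camera adjusted p = 0.685, with a test direction opposite to the median), and the fall of Ifi205 by 0.99 ± 0.10 was the clearest. Without control replicate 2 that list had 5 lower members, without CCl4 replicate 2 it had 7, and without CCl4 replicate 1 it had 1 higher and 1 lower. As TPM 9 were lower, and with TMM 3 were higher and 3 lower. Of 15 MHC genes 0 rose and 3 fell (0 and 2 adjusted over the list alone; median -0.41, camera adjusted p = 0.05, under the threshold before rounding; adjusted p = 0.856 with an estimated correlation), led by H2-K1, from 128 ± 12.4 to 69.6 ± 15.7 FPKM, whose sequence resembles that of other class I genes. That call was lost without control replicate 1 (adjusted p = 0.169), control replicate 3 (0.0717), CCl4 replicate 1 (0.0643) or CCl4 replicate 3 (0.204), as TPM (0.113), with library weights (0.0703) and at a mean FPKM of at least 5 (0.111). The lower members numbered 6 without control replicate 2, 7 without CCl4 replicate 2, 1 without CCl4 replicate 1 or CCl4 replicate 3, 8 as TPM and 1 with quantile scaling. Complement and coagulation genes had 4 higher and 2 lower of 24 (4 and 2 adjusted over the list alone; median 0.03, camera adjusted p = 0.189; adjusted p = 0.0104 without control replicate 3), with the coagulation inhibitor Tfpi falling by 0.91 ± 0.09. Without CCl4 replicate 1 that list had 2 higher members, and without CCl4 replicate 2 or CCl4 replicate 3 it had 1 higher and 1 lower. Its median lay between -0.06 and 0.09 when single libraries were left out.

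Vasoactive, adrenergic and angiotensin genes had 4 higher and 8 lower of 32 (5 and 9 adjusted over the list alone; median -0.24, camera adjusted p = 0.67). The list had 3 higher and 15 lower as TPM. Without control replicate 3 it had 6 and 6, with a median of -0.14, which was also the median without CCl4 replicate 1. Agt, the precursor of angiotensin, rose from 0.977 ± 0.211 to 6.47 ± 1.31 FPKM. The glucocorticoid-induced genes Fkbp5 and Tsc22d3 fell from 9.54 ± 2.74 to 1.35 ± 0.307 FPKM and from 34.3 ± 2.59 to 12.6 ± 1.0 FPKM. The beta-adrenergic receptor Adrb1 had a log2 fold change of 0.07 ± 0.20 (SE; adjusted p = 0.809). Among growth factor genes 3 of 24 rose and 6 fell (4 and 6 adjusted over the list alone; median -0.07, camera adjusted p = 0.795, with a test direction opposite to the median), with Etv5, a transcription factor downstream of FGF signalling, falling from 8.06 ± 0.555 to 2.66 ± 0.148 FPKM. That list's median was -0.16 without control replicate 2, -0.11 without CCl4 replicate 3, -0.01 without CCl4 replicate 1 and 0.03 without control replicate 3, where 5 were higher. It was 0.02 with TMM, quantile or median-ratio scaling and -0.22 as TPM. Of 8 bile acid and nuclear receptor genes 4 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.31, camera adjusted p = 0.346; fry adjusted p = 0.0174). The liver X receptors Nr1h2 and Nr1h3 and their target Abca1 fell by 0.42, 0.44 and 0.56.

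Heart muscle genes changed in both directions. Of 32 cardiomyocyte markers 6 rose and 4 fell (6 and 4 adjusted over the list alone; median 0.11, mean -0.06, camera adjusted p = 0.0378 for a rise; adjusted p = 0.584 with an estimated correlation). Myh7, on chromosome 14 at 54970684 to 54994626, fell by 3.50 ± 0.45 (SE), and its antisense transcript Mhrt rose from 11.7 ± 4.48 to 54.0 ± 6.30 FPKM. The row of the microRNA gene Mir208b, at 54975700 to 54975776 within Myh7, was at 20.1 ± 21.1 and 68.2 ± 10.1 FPKM (adjusted p = 0.0226), and lost its call when any library but control replicate 1 was left out (adjusted p 0.0509 to 0.0782), with no filter (0.0949) or with robust variances (0.102). Without the strand setting, fragments of Mhrt and Myh7 cannot be fully told apart. Mir208b lies on the same strand as Myh7. Myh6, the fast myosin of adult mouse heart, was at 1303 ± 600.2 and 2115 ± 241.7 FPKM (0.78, adjusted p = 0.0542), and at 1.14 (adjusted p = 0.000544) without control replicate 1. It also passed with TMM (0.0422) and median-ratio scaling (0.0418), with mitochondrial rows removed (0.0396), with library weights (0.0164), with the replicate block (0.0191) and at a mean FPKM of at least 5 (0.0444). The skeletal actin Acta1, present in fetal and stressed heart, rose from 28.3 ± 9.97 to 136 ± 31.7 FPKM, the creatine kinase Ckmt2 rose by 0.75 ± 0.16, and Myoz2 and Fabp3 fell by 0.81 ± 0.07 and 0.63 ± 0.10. The list's call was lost without control replicate 3 (adjusted p = 0.0717), without CCl4 replicate 1 (0.131), with no filter (0.0821), with library weights (0.0534) and with TPM (0.0558, median -0.05), TMM (0.0707), quantile (0.161) or median-ratio scaling (0.0743), and 10 members were higher without control replicate 1.

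Among other cell types, smooth muscle and pericyte genes rose in 7 of 20 and fell in 1 (7 and 1 adjusted over the list alone; median 0.06, camera adjusted p = 0.00859; adjusted p = 0.668 with an estimated correlation), with Smtn rising from 17.2 ± 1.57 to 32.1 ± 1.84 FPKM. The median ranged from -0.03 (without CCl4 replicate 2, adjusted p = 0.0581) to 0.18 (without CCl4 replicate 1) when single libraries were left out, was 0.04, 0.11 and 0.09 without control replicates 1, 2 and 3, and was -0.09 as TPM, and 4 members were higher without CCl4 replicate 3. Endothelial genes were split with 4 higher and 5 lower of 26 (4 and 6 adjusted over the list alone; median -0.08, camera adjusted p = 0.542, with a test direction opposite to the median). The lipase anchor Gpihbp1 of capillaries fell from 31.3 ± 1.64 to 17.7 ± 1.88 FPKM, and the VEGF receptor Kdr rose by 0.53 ± 0.09 (SE). The endothelial list had 2 higher and 10 lower as TPM, and 8 and 5 with TMM, quantile or median-ratio scaling. Without control replicate 2, CCl4 replicate 2 or CCl4 replicate 3 it had 2 higher members. Of 20 macrophage genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; median -0.05, camera adjusted p = 0.998). The abundant macrophage marker Lyz2 was at 86.1 ± 11.5 and 92.8 ± 6.64 FPKM (adjusted p = 0.46), and the scavenger receptor Cd163 of resident macrophages fell from 6.27 ± 0.75 to 2.73 ± 0.662 FPKM.

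All 5 erythroid genes tested were higher in CCl4 (5 adjusted over the list alone; median 1.69, camera adjusted p = 0.00232; adjusted p = 0.61 with an estimated correlation). Hbb-bs, an adult beta globin, was at 389 ± 314 and 1006 ± 304 FPKM, and Hbb-bt, its near-identical copy, at 186 ± 158 and 524 ± 149 FPKM, so the split between them is uncertain. Erythroid genes took 0.667% ± 0.515 of the sum left without mitochondrial rows and their pseudogene copies in control and 1.91% ± 0.56 in CCl4 libraries (SD, n = 3 each; exact permutation p = 0.1). No member passed with no filter, with robust variances or without control replicate 2, control replicate 3, CCl4 replicate 2 or CCl4 replicate 3, and 3 passed without CCl4 replicate 1. With under 5 tested members each, 6 cell type lists were not tested as groups. Their called members were 1 higher and 1 lower of 4 mesothelial genes, 1 higher and 2 lower of 4 adipocyte genes, and 1 lower of 2 hepatocyte genes, the last being the plasma protein gene Ahsg, at 4.52 ± 2.23 and 0.813 ± 0.232 FPKM. None of the 2 lymphocyte, 2 granulocyte and mast cell and 3 Schwann cell genes tested passed in limma.

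The remaining genes with the largest changes belonged to no common list. Bdh1, a ketone body dehydrogenase on chromosome 16 at 31422280 to 31458901, had the largest rise, from 4.62 ± 1.36 to 36.9 ± 1.84 FPKM (log2 fold change 2.78 ± 0.15, SE; adjusted p = 6.94e-05). The apelin receptor Aplnr rose from 1.61 ± 0.668 to 11.4 ± 0.335 FPKM, the carboxypeptidase-like secreted protein Cpxm2 from 1.61 ± 0.527 to 12.3 ± 0.824 FPKM, the tubulin Tuba4a from 48.3 ± 15.7 to 170.9 ± 11.3 FPKM, and Rom1, known from photoreceptor membranes, from 3.73 ± 0.584 to 16.4 ± 2.54 FPKM. On the log2(FPKM + 1) scale the largest fall was in 1 of the 2 rows named Nnt, the mitochondrial transhydrogenase, from 73.4 ± 15.4 to 2.51 ± 0.318 FPKM (-4.39 ± 0.15, adjusted p = 1.21e-05). GENCODE places 2 overlapping models of that name on chromosome 13, at 119335448 to 119408997 and at 119335528 to 119408952, and the table does not say which row is which. The other Nnt row was at 115 ± 40.6 and 100.5 ± 8.94 FPKM (adjusted p = 0.708). The insulin receptor substrate Irs2 fell from 11.6 ± 7.98 to 1.11 ± 0.263 FPKM, the desaturase Scd4 from 8.81 ± 2.90 to 0.51 ± 0.212 FPKM, the galectin Lgals4 from 65.4 ± 7.77 to 11 ± 2.57 FPKM, and the salt-inducible kinase Sik1 from 17.5 ± 6.70 to 2.80 ± 0.815 FPKM.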

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

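The rescaling without mitochondrial rows and their pseudogene copies, and for the lists also TPM, median-ratio scaling, the 0.01 pseudocount and limma without trend, with robust variances or with library weights, were chosen after the data were seen. The 3501 calls became 2165 (655 higher, 1510 lower) at a mean FPKM of at least 5, where fewer genes are tested, and 273 (100 and 173) when a log2 change of at least 1 was also required. The split into higher and lower was 617 and 4221 as TPM, 1700 and 1605 with TMM, 1722 higher with quantile and 1713 and 1574 with median-ratio scaling. These scale the libraries in different ways, and which fits the tissue was not tested. Leaving out single libraries gave 2188 to 3258 calls, 642 to 1137 higher and 1546 to 2121 lower. The lowest came without CCl4 replicate 3 (2188, 642 and 1546), and without control replicate 2 it was 648 that were higher. Fewer libraries lower the power of each fit.

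Of the 17 called lists, 1 (0 higher, 1 lower) was called with an estimated correlation. Fry called 10 lists (1 higher), 7 of the 17 and 3 that camera did not call. The 10 lists called by camera only were those of collagen and matrix genes, matrix proteases, myofibroblast genes, MHC genes and cholesterol synthesis. The others were oxidative phosphorylation subunits and the fibroblast, cardiomyocyte, smooth muscle and erythroid markers. Among the 17 called lists the estimated correlation ran from -0.0105 (NRF2 and antioxidant genes) to 0.994 (erythroid genes), against the preset 0.01. It was 0.522 for collagen and matrix genes, 0.538 for fibroblast markers and -0.00951 for the fatty acid list, which kept its call. The NRF2 list lost its call, and the camera adjusted p of the fatty acid list went from 1.8e-09 to 0.0498. Both of these estimates lay below the preset, so a high correlation does not account for every loss or weakening. Beyond these values the cause of the differences was not tested. With the replicate number as a block 2651 genes passed. Deviations of same-numbered libraries correlated at -0.064, 0.0461 and -0.038, and not every library correlated best with its own number. No pairing by number was seen. Deviations from the mean of 3 libraries are tied to each other, so these values cannot exclude a pairing. Under quantile scaling, which gives all libraries the same top values, mt-Nd1 went to -0.0282 and the median of the mitochondrially encoded list to 0. Of the alternative values of 208 named genes, 3686 kept direction and side of the threshold, 185 fell short of it, 32 newly passed it and 1 reversed. For the 32 lists these numbers were 607, 54, 6 and 1. Depth, an estimated 30800000 to 42000000 fragments, and 3 libraries per group limit small changes: 54.9% of simulated changes of 0.5 were recovered. Those runs had far fewer changed genes than were called here and independent errors, so recovery in the data may differ.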

Other observations

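Tests of glucocorticoid or feeding state, of mouse substrain and of other splits were set before their results were seen. Those of glucocorticoid or feeding state and of substrain followed up patterns already seen in the same libraries. The others below (the sum of the Nnt rows, the collagen scores, the heat-shock genes, and scaling) were chosen afterwards. Genes listed by hand as responding to glucocorticoids or fasting were lower in CCl4 libraries. Of 18 tested, 13 fell and 1 rose. The rise was that of Lpin1 (adjusted p = 0.0496), a call lost with pseudocounts of 0.1 or 0.01, with no filter, as TPM, without trend, with the replicate block and without any single library but control replicate 1, while 13 fell in each of these. Of these, Tsc22d3, Sesn1, Cebpd, Cpt1a and Ppargc1a also stand in fixed lists, and of the 13 in no fixed list 8 fell and 1 rose (median -0.72). The transcription factor Klf15 fell from 26.7 ± 5.38 to 11.7 ± 1.04 FPKM (SD, n = 3 each), the kinase Sgk1 from 15.4 ± 1.39 to 7.11 ± 0.765 FPKM, Foxo3 from 17.9 ± 3.05 to 7.36 ± 0.694 FPKM and Hif3a from 1.90 ± 0.355 to 0.153 ± 0.0945 FPKM. Apln, which encodes the ligand of the apelin receptor Aplnr, rose with its receptor, from 0.52 ± 0.233 to 3.34 ± 0.335 FPKM (adjusted p = 0.000194 in limma), and was singled out after its values were seen.

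Genes of atrial muscle differed between libraries of the same group. Control replicate 3 had 1501 FPKM of Nppa, 16.2 of Bmp10, 57.2 of Myl7, 19.9 of Sln and 11.3 of Myl4. In control replicates 1 and 2 Nppa was at 221 and 272 FPKM, Bmp10 at 0, Myl7 at 8.56 and 2.69, Sln at 1.36 and 0.49 and Myl4 at 1.99 and 0.73. CCl4 replicate 3 had 39.3 FPKM of Myl7, 5.32 of Sln and 7.15 of Myl4, with 227 of Nppa and 0.01 of Bmp10. These genes were singled out after their values were seen, and groups of 3 were not tested for outliers.

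The row of Nnt that fell was 35.0% to 46.2% of the sum of both Nnt rows in control libraries and 2.21% to 2.64% in CCl4 libraries. The sum of both rows fell from 188.9 ± 54.6 to 103 ± 9.15 FPKM (SD, n = 3 each). Its log2 fold change in limma was -0.83 (95% interval -1.29 to -0.37). A different split of fragments between the 2 overlapping models would leave this sum unchanged only if both models had the same length. FPKM divides by that length, which is not known for these rows, so the sum cannot decide whether the split is the cause. The Nnt gene is known to be partly deleted in C57BL/6J and intact in C57BL/6N mice. Wdfy1 (log2 fold change -0.13, interval -0.34 to 0.07) and Entpd4b (0.13, -0.09 to 0.35) were recalled as also differing between these substrains. Wdfy1 lay at only 1.04 to 1.47 FPKM, where the log2(FPKM + 1) scale understates a change, so it weighs little. Entpd4b, at 7.69 to 10.1 FPKM, argues against different substrains in the groups only as far as this remembered marker holds. A regulation of Nnt by CCl4 treatment stays open and untested.

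Over 14 collagen genes the mean difference between groups was 1.43 (95% interval 0.87 to 1.98, log2 with a pseudocount of 0.1), and over 18 other fibroblast markers 0.53 (-0.03 to 1.08). The collagen difference exceeded that of the other markers by 0.90 (0.70 to 1.10). Were a larger share of fibroblast RNA the whole cause, both would rise alike only if the other markers came from fibroblasts alone. Some of them, such as Cd34, are also made by other cells, which could damp or add to their rise. Cd34 itself rose by 0.998 in limma (adjusted p = 0.00282). The other markers were split, with 9 of the 18 called higher, among them Lum at 1.59. Among those not called were Pdgfra, Tcf21, Dcn and Gsn, at -0.11, 0.17, -0.29 and -0.18. The scores therefore cannot decide whether a larger share is the whole cause, and a larger share may account for part. Scaling is argued against as the cause of the collagen rise, since the lowest median of the collagen genes under any other scaling was 1.05. Neither collagen expression per fibroblast nor which cells carry the collagen transcripts was tested.

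For the lower stress and fasting genes, scaling is argued against, since the highest median of the immediate early list under any other scaling was -0.93. The 18 glucocorticoid and fasting genes had a median of -0.89 (camera p = 3.05e-06, and p = 0.042 with an estimated correlation). The 13 of them in no fixed list had a median of -0.72 (camera p = 0.0008 with the preset correlation). These genes were listed to follow up a fall already seen in the same libraries, so they are not independent support. A difference in glucocorticoid exposure, feeding state or, not tested here, time of killing between the groups may contribute, through handling or disease. Heat and handling stress during isolation cannot be told apart from it, since the 8 heat-shock genes had a median of -0.37, with 4 lower, against -1.24 for the 27 other members. Under other scalings the heat-shock median lay between -0.23 (quantile) and -0.53 (TPM), and 0 of the 8 were called with TMM or median-ratio scaling, with no filter, with the replicate block and without control replicate 2, CCl4 replicate 2 or CCl4 replicate 3. Without control replicate 3 or CCl4 replicate 1 it was 2. Fibroblast and heart muscle cells were not separated in these tests, and CCl4 itself stays open as a cause.

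For the 3501 changed genes as a whole, the 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05: only 1 of the 10, the real split, gave as many, and the highest other split gave 1 gene. Every other split mixes control and CCl4 libraries, so the difference between the groups widens the spread within it. Few calls there therefore do not show how many genes would pass by chance.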
